A study of Arabidopsis thaliana with 24 samples.

How the data were processed

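RNA was taken from whole rosettes of Arabidopsis thaliana, the wild type Col-0 and jaz4-1, a T-DNA insertion line of the jasmonate repressor gene JAZ4. Plants grew on soil under a 12 h photoperiod and were cut at ZT0 (dawn), ZT6, ZT12 (dusk) and ZT18. Each of the 8 combinations of line and time had 3 libraries, each made from pooled rosettes described as a separate biological replicate, which gave 24 libraries. Per the labels' protocols, RNA was column-purified, NEBNext Ultra libraries were made and an Illumina instrument read both ends. Read totals per library are given with the results; 3 libraries per group limit the precision of each difference. Whether the library kit kept strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

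Per the submitters' processing notes, reads were handled with HISAT2 and featureCounts against the TAIR10 build; versions and settings are not given in the sources used here. The deposited table held 24503 genes, of which 120 were chloroplast and 86 mitochondrial genes, and 23 carried bare numbers as names. In all, 24297 locus identifiers matched the RefSeq annotation of assembly TAIR10.1, which was used only for names and for which genes overlap or neighbour each other. The per-library columns are called RPKM per the file headers, but the values did not depend on gene length. They were whole read counts divided by 1 size factor per library, a signal unit: after multiplication by that factor 100% of values lay within 0.001 reads of a whole number, with a largest distance of 6.92e-05. The deposited factors equalled median-of-ratios factors computed within each time, to a relative distance of at most 4.87e-11. The authors therefore scaled each time apart, and their factors differed by 6.89% to 17.3% from factors computed over all 24 libraries. Deposited signal values are comparable between the lines at a time but not across times. The deposited averages equalled the mean of their replicates to within 1.16e-10.

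The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene and time. Per the file headers the p-value is from a Student's t-test, but only 1.43% of p-values recomputed with that test fell within 0.001 of the deposited p-value. These columns were used only where the authors' deposited table is named.

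The test written down beforehand was edgeR's quasi-likelihood test for counts, or limma-trend on log2(value + 1) if the table held normalised values. Because the table held normalised values, limma-trend (limma 3.58.1, R 4.3.3) with robust empirical Bayes was used on the deposited values with a pseudocount of 1. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. A total of 19614 genes passed edgeR's filterByExpr (minimum count 10, minimum total count 15). All 24 libraries were fitted with 1 coefficient per line and time, 16 residual degrees of freedom and a median prior of 6.24. The contrasts were jaz4-1 minus Col-0 at each time, their average over the 4 times, the dependence of the difference on time (F test) and the change over time within each line (F test). Tests of change over time within each line used the recovered reads scaled over all 24 libraries. The dependence of the difference on time was tested on the deposited values, from the differences between the lines within each time. Adjusted p is Benjamini-Hochberg from limma unless another tool is named, and a gene was called at an adjusted p under 0.05.

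The groups, the designs, the 22 gene lists, the rule for named genes and the alternatives were also chosen before the data were examined. The lists were JAZ repressors, jasmonate synthesis, jasmonate catabolism, jasmonate response, salicylate and immunity, circadian clock, flowering, senescence, cold, abscisic acid and drought, aliphatic glucosinolates, indole glucosinolates, flavonoids and anthocyanins, photosynthesis, growth with PIF and auxin genes, starch breakdown, sugar starvation, touch and rapid stress, heat shock, iron deficiency, root markers and floral organ markers. Lists with 3 or more measured members were tested with camera (limma) on log2 CPM of the recovered reads (edgeR 4.0.16, prior count 2, TMM) with an inter-gene correlation of 0.01, adjusted over all lists and contrasts. A camera test asks whether a list's genes rank differently from all other genes. The alternative fry asks whether a list's genes move, on balance, one way, without comparison to other genes. A first run of camera used log2(value + 1) instead and is kept as an alternative.

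Named genes were JAZ4 first. At each time they were called genes with a symbol, a mean of at least 1 CPM and no overlap between the 3 libraries of each line, taking the 8 largest and 8 smallest log2 fold changes. On average over times, the same sign at all 4 times replaced the overlap condition. Up to 3 called members of each list with the smallest p, up to 10 genes called at all 4 times, the 10 genes with the smallest p for dependence on time among those with a symbol and a mean of at least 1 CPM, and 9 core clock genes were also named. Of the 89 genes chosen in this way, 22 overlap another gene in TAIR10.1.

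For the 25 clock genes a cosinor of period 24 h was fitted to log2 CPM per line, and the median phase difference was tested by permuting line labels within each time (100000 resamples, 2-sided). For JAZ4, mean CPM was compared by an exact permutation test within times over 160000 divisions of the libraries. A gene with 0 reads in a group was set against a floor of 3 reads over the group, and a fold against it is a lower bound; 3 reads are 0.132 to 0.178 CPM in a single library. Intervals (95%) and floors cover counting error only, since reads from PCR libraries are not independent molecules.

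The alternatives fixed with the design were size factors over all 24 libraries in place of the deposited ones, organelle genes left out before the within-time size factors, no filter, a mean of at least 1 CPM, a log2 fold change of at least 1, DESeq2 1.42.0, limma-voom, a replicate block, only the libraries compared, other prior counts, an estimated inter-gene correlation, fry and each library left out in turn. The former pair were meant for TMM and were adapted to the scaling found in the table. At a single time, calls of single named genes and camera calls of single lists were followed only without libraries of that time. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test and TMM scaling on the recovered reads, pseudocounts of 0.5 and 4, length and GC trends removed, the log2(value + 1) list values, and the fit without the 2 libraries with the fewest detected genes. A test of collection time at ZT6 was replaced after its first form proved to be fixed by a value already seen.

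The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 19614. At single times limma-trend recovered 57% to 64% of the 2-fold and 86% to 93% of the 4-fold changes, with 2.0% to 7.27% false calls. On average over times it recovered 89% and 97%, with 7.92% false calls, and for dependence on time 33% and 78%. For change over time it recovered 65% of 2-fold and 97% of 4-fold changes in Col-0 and 67% and 90% in jaz4-1. DESeq2 gave 13.7% false calls at ZT6, 14.8% on average and 17.7% for dependence on time. A phase shift of 2 h was simulated apart, in cosines of period 24 h with added noise and not in counts, and was recovered as 1.90 h. These curves follow the fitted model, so the value does not cover genes with another course over the day. A list raised 2-fold gave an adjusted p of 1.41e-31, or 1.23e-05 with an estimated correlation. The simulated genes were drawn independently of each other, and the changed ones were taken from genes with higher mean counts. These rates therefore leave out deviations that genes of a library share. When the real libraries were split against their labels, 1 split at ZT0 gave 1008 calls, and splits within times gave a median of 30 list calls. Python 3.11.15 with matplotlib 3.10.9 drew the figures.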

Results

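Gene expression was measured by RNA-seq in rosettes of Col-0 and jaz4-1 at 4 times of a day with 12 h of light. The series asks how a line with an insertion in JAZ4, a repressor of jasmonate signalling, differs from the wild type over the day. Each line had 3 libraries at ZT0, ZT6, ZT12 and ZT18. Read totals per library were 16832200 to 22644700 (median 20068900), and 18959 to 21863 genes had at least 1 read (median 21069). The fewest genes were detected in Col-0 at ZT0 replicate 2 (18959) and in jaz4-1 at ZT6 replicate 2 (19151). The 10 most abundant genes took 7.31% to 14.9% of the reads. The chloroplast share of reads at ZT6 was 0.150% ± 0.146 in jaz4-1 and 0.0341% ± 0.00380 in Col-0 (SD, n = 3; exact permutation p 0.1, 2-sided, the smallest that 3 against 3 libraries allow).

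JAZ4 (AT1G48500) was near the detection floor in both lines and lower in jaz4-1. Over 12 libraries per line it had 31 reads in jaz4-1 and 93 in Col-0, or 0.131 ± 0.120 against 0.387 ± 0.298 CPM (SD, n = 12). The difference passed an exact permutation test within times (p 0.00936, 2-sided), and the ratio of Col-0 to jaz4-1 was 2.96 (95% counting interval 1.95 to 4.60). In jaz4-1 and Col-0 respectively, the 3 libraries together held 6 and 17 reads at ZT0, 12 and 15 at ZT6, 7 and 33 at ZT12, and 6 and 28 at ZT18. Single libraries held 0 to 8 reads in jaz4-1 and 0 to 23 in Col-0. The limma difference on average was -1.24 ± 0.50 on the log2 scale (adjusted p 0.152) and was not called. At ZT6 the value of -0.57 turned to 0.36 without jaz4-1 replicate 2. In the authors' deposited table the log2 fold changes of JAZ4 were -0.08, -0.02, -0.17 and -0.11 from ZT0 to ZT18. Its values for QQS and PCC1 at ZT0 (-0.60 and 1.28 in the authors' deposited table) also lay nearer to 0 than those of limma here (-5.95 and 5.96), so its JAZ4 values do not show that the gene was unchanged. The table gives 1 value for the whole gene, so reads before and after the insertion are not told apart.

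At dawn (ZT0), 181 of 19614 genes were called, 144 higher and 37 lower in jaz4-1. Among genes with a symbol, a mean of at least 1 CPM and no overlap between the lines, PCC1 (AT3G22231), a small membrane protein controlled by pathogens and the clock, had 1199 ± 912 normalised reads in jaz4-1 and 15.7 ± 5.46 in Col-0 (SD, n = 3), a log2 fold change of 5.96 ± 0.64 (SE; adjusted p 8.09e-05). LURP1, a gene of basal defence against downy mildew, rose by 5.96. The ankyrin-repeat genes BAD1 and ACD6, of which ACD6 promotes salicylate accumulation, rose by 4.81 and 3.38. WRKY58 rose by 4.66, EDS1B, a lipase-like immunity gene, by 3.89, and PCR1 by 3.55. The haem oxygenase gene HO3 had 2 reads in the Col-0 libraries and 133 in those of jaz4-1. Of 19 measured salicylate and immunity genes, 6 rose and the others did not pass: WRKY54 (2.85 ± 0.36), WRKY70 (2.33 ± 0.31), SARD1 (1.94), NPR4 (0.92 ± 0.12), EDS1 (0.63) and NPR1 (0.56). Adjusted over the list alone, 8 rose. SARD1 is an activator of salicylate synthesis genes, and NPR4 is a salicylate receptor. The list ranked higher in jaz4-1 (median 0.63; camera adjusted p 2.24e-11; adjusted p = 0.0995 with an estimated correlation).

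The lower genes at ZT0 were led by QQS (AT3G30720), an orphan gene linked to starch content, with 13.4 ± 12.9 normalised reads in jaz4-1 and 646 ± 308 in Col-0 (SD, n = 3; -5.95 ± 0.72, adjusted p 0.000148). The methylesterase gene MES8 (AT2G23590) fell by 2.37 on the log2 scale. Smaller falls were seen in FLZ8 (-1.15), ATRAD51C (-0.98), the sterol methyl oxidase gene SMO1-3 (-0.98), SCPL7 (-0.94), the transporter genes ABCG41 (-0.85) and ER-ANT1 (-0.72). In the authors' deposited table, MES8 alone of these lower genes had an adjusted p under 0.05 at ZT0 (4.31e-06). There it was 0.0760 for QQS and 0.0852 (SCPL7) to 0.717 (ABCG41) for the others. Adjusted p of the genes named at ZT0 lay between 5.76e-09 for AT1G64795, described further on, and 0.0417 for NPR1. Without single libraries the count was 118 (Col-0 replicate 1), 97 (Col-0 replicate 2), 663 (Col-0 replicate 3), 93 (jaz4-1 replicate 1) and 101 (jaz4-1 replicate 3), and 117 without the 2 libraries with few detected genes, where 4 of the immunity list rose. FLZ8, ATRAD51C, SMO1-3, SCPL7, ABCG41, ER-ANT1 and PCR1 lost their calls when Col-0 replicate 1 or 2 or a jaz4-1 replicate was left out (highest adjusted p 0.165), and 3 immunity list members rose without Col-0 replicate 1 or jaz4-1 replicate 3. With limma-voom PCC1, LURP1, HO3, PCR1, FLZ8, ATRAD51C, SCPL7 and ABCG41 were not called (adjusted p up to 0.361), and with only the ZT0 libraries fitted WRKY58, HO3, NPR4, AT3G29644, FLZ8, ATRAD51C, SMO1-3, SCPL7, ABCG41 and ER-ANT1 were not (up to 0.813). PCR1 was not called by edgeR, and PCR1, FLZ8, ATRAD51C, SCPL7 and ER-ANT1 not without both libraries with few detected genes (up to 0.0973).

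**Figure D1:**
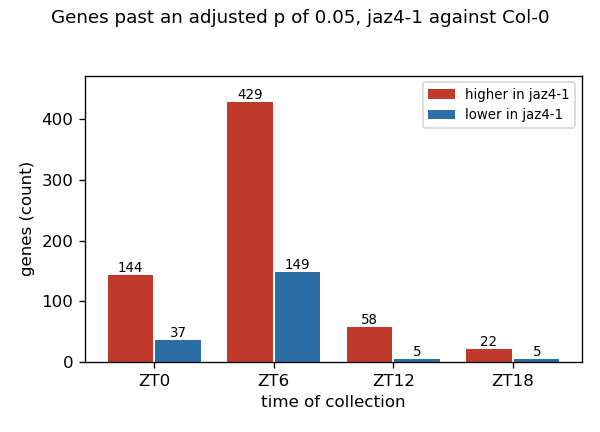
Bars give the number of genes called in jaz4-1 against Col-0 (limma, adjusted p under 0.05, 3 libraries per line and time) at each collection time on the x axis, higher in red and lower in blue. Counts of higher genes were 144, 429, 58 and 22 from ZT0 to ZT18 and exceeded those of lower genes (37, 149, 5 and 5) at each time.

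At ZT6, in the middle of the light period, 578 genes were called, 429 higher and 149 lower in jaz4-1. Immunity, sugar starvation and touch genes were among those that rose, and genes of glucosinolate synthesis among those that fell. Among genes with a symbol, a mean of at least 1 CPM and no overlap between the lines, the 8 largest rises were in NHL13 (2.77), the pectin methylesterase gene PME41 (2.50), SARD1 (2.35), BT2 (2.32), XTH23 (2.17), DMR6, a salicylate hydroxylase (2.17), HR3, a homologue of the mildew resistance gene RPW8 (2.11), and the cytokinin synthesis gene IPT1 (2.06). BT2 (AT3G48360), a BTB scaffold protein, had 4611 ± 535 normalised reads in jaz4-1 and 985 ± 439 in Col-0 (SD, n = 3; SE 0.29, adjusted p 0.000221). Of the 19 salicylate and immunity genes 5 rose, namely SARD1, WRKY54 (2.01), NPR3 (1.32), WRKY70 and NPR4 (0.58). Adjusted over the list alone, 9 rose, and the list ranked higher (median 0.45; camera adjusted p 1.65e-06; adjusted p = 0.196 with an estimated correlation).

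Of 7 sugar starvation genes at ZT6, 4 rose, or 5 adjusted over the list alone. DIN10 (AT5G20250), a dark-inducible gene, rose by 1.79 ± 0.29 (adjusted p 0.00178), with 12540 ± 3179 normalised reads in jaz4-1 and 3568 ± 551 in Col-0 (SD, n = 3). The class II trehalose-phosphate synthase genes TPS8, TPS11 and TPS9 rose by 1.21, 1.16 and 0.99. The list ranked higher (median 1.16; camera adjusted p 1.43e-05; adjusted p = 0.196 with an estimated correlation). Of 12 touch and rapid stress genes 3 rose: the zinc finger gene SZF1 (1.57), the calmodulin-like gene TCH2 (1.02) and ERF4 (0.71). Adjusted over the list alone 8 rose, with a camera adjusted p of 1.70e-07 (adjusted p = 0.351 with an estimated correlation). Single members of other lists also rose: WRKY53 (1.64) of the senescence list, the floral repressor TEM2 (1.16), the abscisic acid phosphatase PP2CA (0.96), PIF5 (0.78) and the clock gene CHE (0.58).

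By the same conditions, the 8 largest falls at ZT6 were in QQS (-7.36), DUR (-2.45), the flavonol regulator MYB111 (-2.42), MES8 (-2.18), the MADS-box gene AGL15 (-2.13), RBK1 (-1.98), ZHD7 (-1.94) and HTT3 (-1.91). MYC4, a bHLH factor of jasmonate responses, fell by 0.69 (SE 0.14, adjusted p 0.00641) and was the only called member of the 12 measured jasmonate response genes by limma at ZT6. Of 17 aliphatic glucosinolate genes 2 fell, the regulator MYB28 (-0.63 ± 0.15) and FMOGSOX1 (-0.86 ± 0.23), or 12 adjusted over the list alone. That list ranked lower (median -0.77; camera adjusted p 4.05e-09; adjusted p = 0.210 with an estimated correlation). Of 10 indole glucosinolate genes MYB34 (-0.95) and SUR1 (-0.58) fell, or 3 adjusted over the list alone, while the list itself was not called (adjusted p 0.156). HSP18.2 (-1.58) was the 1 heat shock gene of 5 that fell, or 3 adjusted over the list alone (camera adjusted p 0.0240; adjusted p = 0.196 with an estimated correlation).

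Adjusted p of the genes named at ZT6 reached 0.0495 (TEM2), and 31.1% of tested genes did not overlap between the lines, against 10.8% at ZT0, 14.9% at ZT12, 9.13% at ZT18 and 10% by chance. Without single ZT6 libraries the count was 173, 296 and 366 (Col-0 replicates 1 to 3) and 358, 218 and 1208 (jaz4-1 replicates 1 to 3). It was 243 without the 2 libraries with few detected genes, where 3 immunity, 1 sugar starvation, 0 touch and 0 aliphatic glucosinolate genes were called. Of the 40 genes named at ZT6, 17 kept their call without each ZT6 library: BT2, DIN10, DMR6, MES8, MYB34, MYC4, NPR3, PIF5, PME41, QQS, SARD1, WRKY54 and 5 genes called at all times. Calls of single named genes were not followed without libraries of other times. The remaining 23 were lost without Col-0 replicate 1 (23 of them), replicate 2 (18), replicate 3 (12), or jaz4-1 replicate 1 (17), replicate 2 (22) or replicate 3 (3), with adjusted p up to 0.240. AGL15, DUR, MYB111 and RBK1 were not called with limma-voom, edgeR or only the ZT6 libraries fitted, nor were HR3, IPT1 and ZHD7 with limma-voom, HTT3 and TCH2 with edgeR, or HR3, IPT1, HTT3, TCH2 and HSP18.2 with only those libraries (adjusted p up to 0.227). Without both libraries with few detected genes 21 of the 40 were not called (up to 0.232), among them NHL13, XTH23, WRKY53, MYB28 and TPS11. Members called fell to 3 (immunity; Col-0 replicate 1, jaz4-1 replicates 1 and 2), to 1 (sugar starvation; Col-0 replicate 1, jaz4-1 replicate 2) or 2 (jaz4-1 replicate 1), and to 0 (touch; Col-0 replicates 1 and 2, jaz4-1 replicates 1 and 2). Touch calls were also 1 without Col-0 at ZT12 replicate 1, Col-0 at ZT18 replicate 2, jaz4-1 at ZT12 replicate 2 or jaz4-1 at ZT18 replicate 2 or 3, and 6 without jaz4-1 at ZT12 replicate 1 or 3. Aliphatic glucosinolate calls were 0 without Col-0 replicate 1 or 2 or jaz4-1 replicate 2, and 5 without Col-0 at ZT18 replicate 1. They were 1 without Col-0 replicate 2 of ZT12 or ZT18, or without jaz4-1 at ZT0 replicate 1, ZT6 replicate 1, ZT12 replicate 1 or 2 or ZT18 replicate 2.

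**Figure D2:**
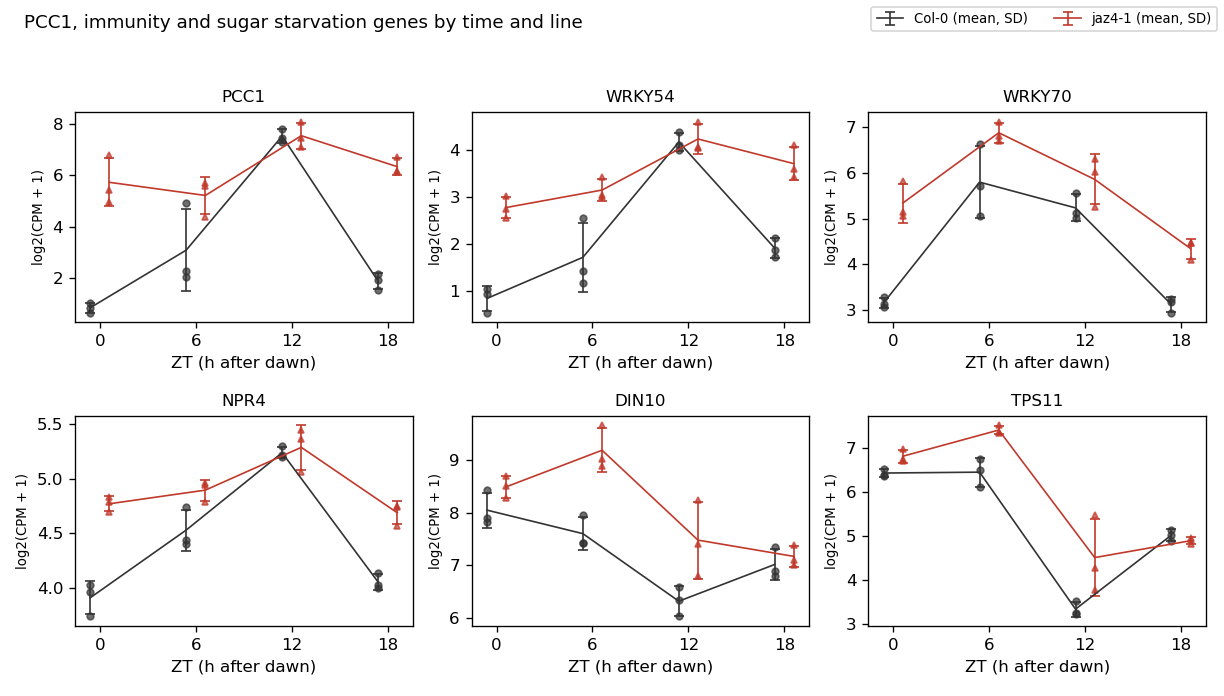
Log2(CPM + 1) on the y axis against hours after dawn (ZT) on the x axis for PCC1, 3 genes of the immunity list and 2 sugar starvation genes, with points for single libraries (3 per line and time), lines through the means and bars of 1 SD. PCC1 was higher in jaz4-1 at ZT0 and ZT18 (log2 fold change 5.96 and 4.90) and near Col-0 at ZT12 (0.05), while DIN10 differed most at ZT6 (1.79).

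At dusk (ZT12), 63 genes were called, 58 higher and 5 lower in jaz4-1. Among genes with a symbol that met the conditions given for ZT6, NAC072, a factor of drought responses, rose by 2.63, TEM2 by 2.49, BT5 by 2.40, BBX29 by 2.34, RAV1, a relative of TEM2, by 2.02, HSPRO2 by 1.98, BT2 by 1.89 and PEX3 by 1.82. RAV1 (AT1G13260) had the smallest p among these (SE 0.21, adjusted p 1.43e-05). The clock gene RVE1 (AT5G17300) rose by 1.58 ± 0.21 (adjusted p 0.000359). QQS (-5.38) and MES8 (-1.75) fell. Of the 7 sugar starvation genes TPS11 rose (1.28, adjusted p 0.0336), while adjusted over the list alone 5 rose and 1 fell. The list ranked higher (median 1.21; camera adjusted p 3.03e-08; adjusted p = 0.106 with an estimated correlation). Of 12 touch genes 0 were called by limma at ZT12, with 10 at an unadjusted p under 0.05, 10 adjusted over the list alone, 1 by edgeR, 7 by DESeq2 and 0 by limma-voom. The touch list at ZT12 had the smallest camera p of the 105 list tests (median 1.37; adjusted p 3.81e-18; adjusted p = 0.106 with an estimated correlation). Of the 19 salicylate and immunity genes 0 were called by limma, adjusted over all genes or over the list alone, with 6 at an unadjusted p under 0.05 and 0 by edgeR, DESeq2 or limma-voom (median 0.55; camera adjusted p 1.20e-05; adjusted p = 0.207 with an estimated correlation).

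Adjusted p of the other genes named at ZT12 reached 0.0336 (TPS11). Over all alternatives the log2 fold change of TPS11 at ZT12 ran from 0.785 to 1.64. Without single ZT12 libraries the count was 28 (Col-0 replicate 1), 30 (Col-0 replicate 2), 126 (jaz4-1 replicate 1), 26 (jaz4-1 replicate 2) and 22 (jaz4-1 replicate 3). BBX29, NAC072, TPS11 and MES8 lost their calls without Col-0 replicate 1, BBX29, NAC072 and TPS11 without Col-0 replicate 2 or 3 or jaz4-1 replicate 2, and BBX29, MES8 and TPS11 without jaz4-1 replicate 3 (adjusted p up to 0.275); 6 touch genes were called without jaz4-1 replicate 1, 2 without Col-0 replicate 3 and 1 without the Col-0 ZT6 replicate 1. With only the ZT12 libraries fitted, 10 of the 17 calls of named genes were lost, those of NAC072, TEM2, BT5, BBX29, RAV1, HSPRO2, BT2, MES8, RVE1 and TPS11 (adjusted p up to 0.584). With limma-voom NAC072, BBX29 and TPS11 were lost (up to 0.696), and BBX29 also with edgeR and DESeq2. Without jaz4-1 replicate 1, 4 sugar starvation genes were called, 2 without the Col-0 ZT0 replicate 1, and 0 without any other ZT12 library or jaz4-1 replicate 1 or 2 of ZT6. Without jaz4-1 replicate 3 the list medians at ZT12 were 0.65 for sugar starvation, 0.82 for touch and 0.24 for salicylate and immunity genes, and without Col-0 replicate 3 that of sugar starvation was 0.78.

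At ZT18, in the night, 27 genes were called, 22 higher and 5 lower in jaz4-1. PCC1 (1577 ± 462 against 52.6 ± 19.1 normalised reads, SD, n = 3) rose by 4.90 ± 0.64 (adjusted p 0.00103), and BAD1 by 4.68. DMR6 rose by 2.70, WRKY54 by 2.14, the wall-associated kinase gene WAK1 by 1.79, RLK1 by 1.79, the lectin-like gene LLP by 1.67 and the calmodulin-like gene CML10 by 1.63. The evening complex gene LUX (AT3G46640) rose by 1.07 ± 0.16 (adjusted p 0.00113). QQS (-5.67), MES8 (-2.00), the methionine sulfoxide reductase gene MSRB5 (-0.88) and APR1 of sulfate assimilation (-0.66) fell. Of the 19 salicylate and immunity genes WRKY54 and NPR4 (0.70) rose, or 5 adjusted over the list alone (median 0.23; camera adjusted p 1.61e-07; adjusted p = 0.196 with an estimated correlation). Adjusted p of the genes named at ZT18 reached 0.0417 (APR1), and the count was 15 without jaz4-1 replicate 3. APR1, MSRB5, RLK1, WAK1, CML10, NPR4 and WRKY54 were lost without at least 1 library: 4 of them without Col-0 replicate 1, 6 without Col-0 replicate 2 or jaz4-1 replicate 1, 3 without jaz4-1 replicate 2 and all 7 without Col-0 replicate 3 or jaz4-1 replicate 3 (adjusted p up to 0.457). With limma-voom PCC1, BAD1, DMR6, LLP and AT5G15420 were not called (adjusted p 0.0535 for AT5G15420 to 1.00 for BAD1), and with only the ZT18 libraries fitted LUX, RLK1, NPR4 and APR1 were not (up to 0.208). Of the immunity list 1 was called without Col-0 replicate 2 or jaz4-1 replicate 1, and 0 without Col-0 replicate 3 or jaz4-1 replicate 3.

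On average over the 4 times, 918 genes were called, 643 higher and 275 lower in jaz4-1. Among genes with a symbol, a mean of at least 1 CPM and the same sign at all 4 times, PCC1 rose by 3.36 ± 0.32 (adjusted p 6.07e-06), BAD1 by 2.89, LURP1 by 2.79, HO3 by 2.70, PCR1 by 2.49, HR3 and DMR6 by 2.06 and ACD6 by 1.81. Of the 19 salicylate and immunity genes 8 rose, all 19 had positive differences, and 14 rose adjusted over the list alone. WRKY54 rose by 1.77 ± 0.18, SARD1 by 1.68 ± 0.20, the pathogenesis-related glucanase gene PR2 by 1.66 ± 0.40 and WRKY70 by 1.41 ± 0.16. NPR3, NPR4, EDS1 and NPR1 rose by 0.67, 0.57, 0.34 and 0.33. The marker PR1 differed by 1.28 ± 0.73 and was not called (adjusted p 0.327). The list ranked higher (median 0.58; camera adjusted p 1.10e-12; adjusted p = 0.0995 with an estimated correlation), and 9 members were called without the 2 libraries with few detected genes.

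Sugar starvation and touch genes were also higher on average. DIN10 (0.91 ± 0.15), TPS11 (0.69), TPS8 (0.66) and TPS9 (0.53) rose among 7 sugar starvation genes, or 5 adjusted over the list alone (median 0.66; camera adjusted p 2.02e-05; adjusted p = 0.196 with an estimated correlation). Of 12 touch genes 8 rose, or 11 adjusted over the list alone, with ZAT10 at 1.25, TCH3 at 1.16 ± 0.20, TCH4 at 1.15, SZF1 at 0.94 and WRKY33 at 0.92 (median 0.91; camera adjusted p 3.06e-10; adjusted p = 0.196 with an estimated correlation). TEM2 (0.82), WRKY53 (0.72), RVE1 (0.56), LUX (0.46), PIF5 (0.42) and PP2CA (0.38) rose as well. QQS (-6.09 ± 0.36), MES8 (-2.08), MYOB5 (-1.33), DUR (-1.09), PME16 (-1.03), CYCB1;5 (-1.02), ATHB-51 (-0.99) and the cold-induced gene RCI2B (-0.99) fell. MYC4 (-0.30 ± 0.07, adjusted p 0.0112) and MYB28 (-0.33) fell by less; MYB28 was the 1 called gene of 17 aliphatic glucosinolate genes, or 5 adjusted over the list alone (median -0.22; camera adjusted p 0.000217; adjusted p = 0.524 with an estimated correlation). The count was 1435 without Col-0 at ZT0 replicate 3 and within 1.5 times of 918 without each other library. Of the 38 genes named on average, 34 kept their call without each library, and ATHB-51, DUR, WRKY53 and PME16 lost theirs without at least 1 of 20 libraries (adjusted p up to 0.101). With limma-voom LURP1, DUR, ATHB-51 and WRKY53 were not called (up to 0.0550), and without both libraries with few detected genes DUR, ATHB-51, WRKY53 and RCI2B were not (up to 0.116). Aliphatic glucosinolate calls were 4 without Col-0 at ZT0 replicate 3 or ZT18 replicate 1, 3 without jaz4-1 at ZT6 replicate 3, and 2 without Col-0 replicate 3 of ZT6 or ZT12.

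A set of 7 genes was called in the same direction at all 4 times, 5 higher and 2 lower in jaz4-1, and their levels did not overlap between the 12 libraries of each line. Over 12 libraries per line, AT3G05945 had 34 reads in Col-0 and 5538 in jaz4-1, AT1G64795 had 2 and 1116, AT1G75945 had 19 and 1112, AT5G15420 had 9 and 986, and AT3G29644 had 168 and 1536. AT3G05945 and AT3G29644 are long non-coding RNAs in TAIR10.1. QQS had 9088 reads in Col-0 and 157 in jaz4-1, and MES8 had 1028 and 229. Where the 3 Col-0 libraries held 0 reads, the fold is a lower bound against a floor of 3 reads over the group. By that measure AT3G05945 was at least 334-fold higher at ZT6, and AT1G64795 at least 27.1-fold, 33.8-fold and 84.9-fold higher at ZT6, ZT12 and ZT18. AT1G75945 was at least 41.9-fold higher at ZT0 and 143-fold at ZT12, and AT5G15420 at least 143-fold and 65.4-fold at those times. AT1G64795 and AT3G29644 overlap another annotated gene, so the gene of origin of their reads is uncertain.

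**Figure D3:**
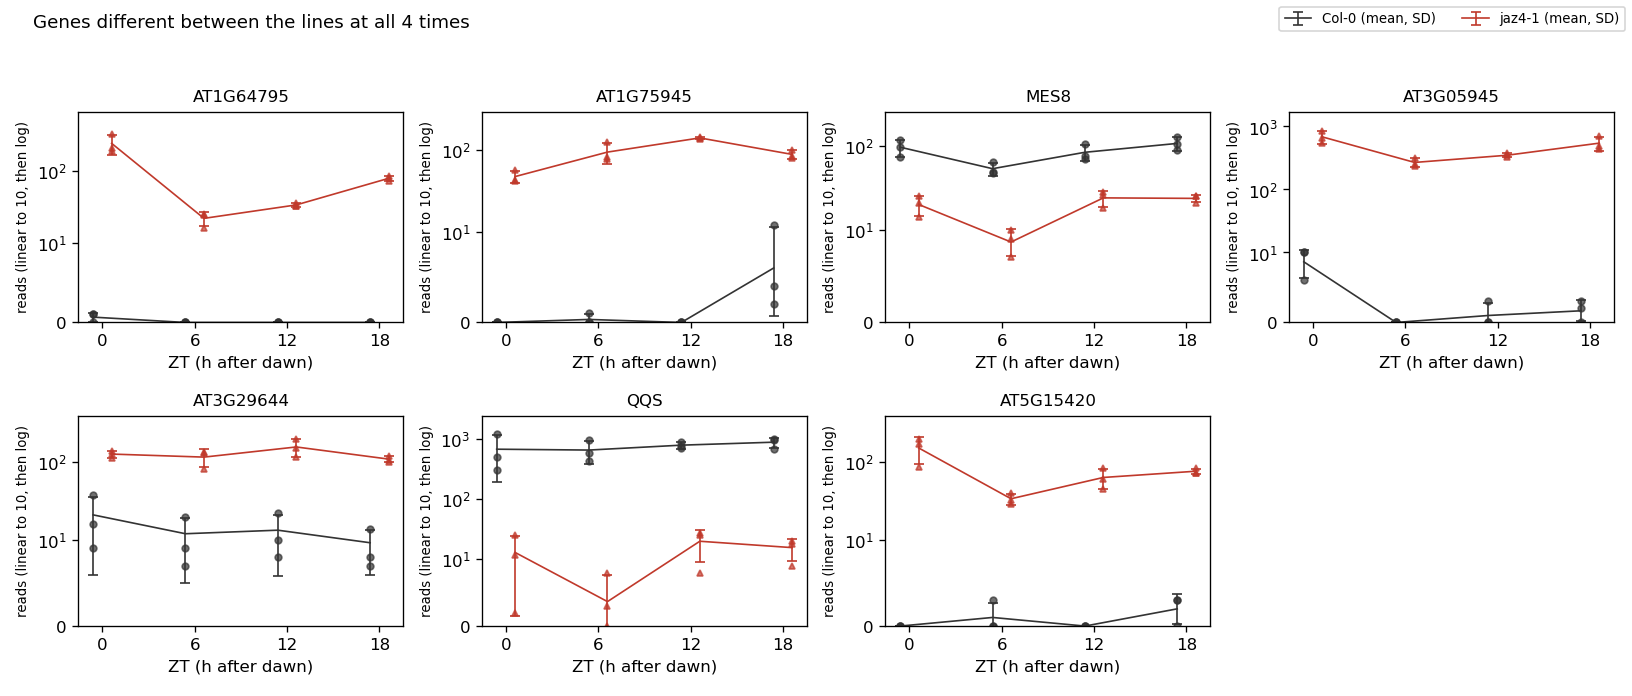
Reads per library on the y axis (linear to 10, then logarithmic) against hours after dawn (ZT) for the 7 genes called at all 4 times, with points for single libraries (3 per line and time), lines through the means and bars of 1 SD. In jaz4-1 the libraries held 235 to 849 reads of AT3G05945 and 0 to 27 of QQS, against 0 to 10 and 313 to 1236 in Col-0.

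The difference between the lines depended on the time in 38 genes (limma's F test of dependence on time). Among those with a symbol and a mean of at least 1 CPM, LLP had the smallest p, with an adjusted p of 0.00299 and log2 fold changes of 1.82, 1.64, -0.73 and 1.67 from ZT0 to ZT18. PCC1 differed by 5.96, 2.53, 0.05 and 4.90 (adjusted p 0.0228), so that it lay near the Col-0 level at ZT12. A group with its largest difference at ZT6 or ZT12 held BT2 (0.23, 2.32, 1.89 and -0.04), BT5 (-0.03, 1.08, 2.40 and -0.54) and TEM2 (-0.19, 1.16, 2.49 and -0.17), with adjusted p of 0.0207, 0.0173 and 0.0207. The smallest p lay at ZT0 for 11 of the 38 genes, at ZT6 for 14, at ZT12 for 12 and at ZT18 for 1. The count was 7 without Col-0 at ZT12 replicate 1, 16 and 60 without jaz4-1 at ZT12 replicate 2 or 1, 19 without Col-0 at ZT12 replicate 2, and 17 and 25 without Col-0 at ZT6 replicate 1 or 2. It was 24 and 21 without jaz4-1 at ZT6 replicate 2 or 3, 25 without jaz4-1 at ZT0 replicate 2, 22 without Col-0 at ZT18 replicate 2, 23 and 22 without jaz4-1 at ZT18 replicate 1 or 2, and 5 without both libraries with few detected genes. Of the 10 genes with the smallest p among those with a symbol and a mean of at least 1 CPM, LLP and BT5 kept their call without each single library. BT2, APR1, TEM2, RZPF34, PCC1, Cand1 and OXS3 lost it without Col-0 at ZT12 replicate 1, and OFUT20, Cand1 and OXS3 without Col-0 at ZT6 replicate 1. Further losses came without Col-0 at ZT12 replicate 2 (PCC1, Cand1 and OXS3), jaz4-1 at ZT12 replicate 2 (RZPF34, Cand1 and OXS3) or 3 (OXS3), jaz4-1 at ZT6 replicate 3 (OFUT20 and Cand1) or 2 (Cand1), Col-0 at ZT6 replicate 3 (Cand1) and jaz4-1 at ZT0 replicate 2 (OXS3), with adjusted p up to 0.0939. Of these 10 genes LLP and RZPF34 were the ones called without both libraries with few detected genes, and PCC1 was not called with limma-voom (adjusted p 0.588).

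In all, 748 genes were called at 1 or more times, 672 of them at 1 time only. Higher genes shared by ZT0 and ZT18 numbered 21, where independent lists would share 0.162, and ZT0 and ZT6 shared 40 (3.15 for independent lists). ZT6 and ZT12 shared 24 higher genes (1.27), ZT6 and ZT18 13 (0.481), ZT0 and ZT12 8 (0.426) and ZT12 and ZT18 5 (0.0651). The times share no libraries, but all calls come from 1 fit with a spread per gene shared by all times. A gene with a small spread is called more easily at each time, so the values for independent lists are a reference only. Of the 89 genes chosen by rule, 22 overlap another gene in TAIR10.1, among them BAD1, HO3, EDS1B, SARD1, DIN10, BT5, RVE1, LUX, LLP, APR1, NHL13, WRKY53, TCH2, TCH3 and WRKY33, and EDS1, EDS1B and WAK1 have close copies, so the assignment of their reads is uncertain. Across genes, which are not independent replicates, log2 fold changes of pairs of times correlated with r of 0.109 to 0.306. The authors' deposited table held 106, 1266, 146 and 71 genes at an adjusted p under 0.05 from ZT0 to ZT18. Of these genes of the authors' deposited table, 78, 492, 54 and 27 were also called by limma here. edgeR's quasi-likelihood test on the recovered reads, of which 100% were whole, called 151, 532, 71 and 25 genes from ZT0 to ZT18, 958 on average and 37 for dependence on time.

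Over the day, 9636 genes (49.1%) changed in Col-0 and 10491 (53.5%) in jaz4-1 by limma's F test. Both lines shared 8156 of them, where independent lists would share 5154, and the time of the highest mean was the same for 6454 of the shared genes (79.1%). Both lists came from 1 fit with a shared spread per gene, so 5154 is a reference only. In Col-0, 3685, 2291, 2478 and 1182 genes had their highest mean at ZT0, ZT6, ZT12 and ZT18, and in jaz4-1 3998, 2603, 2770 and 1120. All 25 measured clock genes changed over time in both lines. CCA1 and LHY, the morning MYB factors, peaked at ZT0 in both lines, PRR9, PRR7, PRR5 and GI at ZT6, and TOC1, LUX and ELF4 at ZT12.

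The timing of the clock genes was compared next. The peak time was the same in both lines for 24 of 25 genes, the exception being RVE6. The median phase difference was -0.129 h (jaz4-1 minus Col-0; 17 genes earlier and 8 later; permutation p 0.0691, 2-sided), which was not called. Single differences ranged from -0.82 h (ELF3) to 0.86 h (LUX). No single gene was called (0 by the permutation test with Benjamini-Hochberg adjustment, 3 at an unadjusted p under 0.05; no other tool was run). The median difference of amplitude was -0.02 on the log2 scale (permutation p 0.745). The median phase difference passed at -0.163 h without the 2 libraries with few detected genes (permutation p 0.0160), and without Col-0 at ZT6 replicate 3 (-0.156 h, p 0.0341), Col-0 at ZT12 replicate 3 (-0.149 h, p 0.0438), jaz4-1 at ZT6 replicate 2 (-0.162 h, p 0.0228) and jaz4-1 at ZT18 replicate 2 (-0.168 h, p 0.0228; permutation tests).

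By level, 3 clock genes were called at single times, LUX at ZT18, RVE1 at ZT12 and CHE at ZT6. The test of dependence on time did not pass for LUX (adjusted p 0.182) or RVE1 (0.0671). CHE lost its call without any of Col-0 replicates 1 to 3 or jaz4-1 replicates 1 and 2 of ZT6. CCA1 differed by 0.20, -0.05, -0.05 and 0.43 from ZT0 to ZT18, LHY by 0.14, -0.00, 0.74 and 0.25, and TOC1 by -0.01, 0.42, 0.10 and 0.17, none of them called at any time by limma. The same holds for PRR9 (0.03, -0.33, -0.08 and 0.50), PRR7 (-0.15, 0.28, 0.13 and -1.10), PRR5 (1.15, 0.32, 0.31 and -0.13), GI (0.71, 0.53, -0.07 and 1.00) and ELF4 (0.38, -0.38, -0.07 and 0.23). Some were called by DESeq2, by limma-voom or with 1 library left out. The lowest adjusted p of these fits was 0.000761 for PRR5 at ZT0, 0.00496 for GI and 0.0327 for TOC1 at ZT6, and 0.0386 for LHY at ZT12. On average it was 0.00586 for PRR5, 0.0403 for LHY and 0.0417 for GI. In the authors' deposited table GI at ZT6 had an adjusted p of 0.00782. PRR9 held 3 reads in jaz4-1 at ZT12 and 1 in Col-0 at ZT18. As a list the 25 clock genes ranked higher at ZT12, ZT18 and on average (camera adjusted p 0.0328, 0.0245 and 0.0165; adjusted p = 0.493, 0.467 and 0.464 with an estimated correlation). These camera calls were lost without Col-0 replicate 3 or jaz4-1 replicate 1 or 2 at ZT12, without Col-0 replicate 2 or 3 or jaz4-1 replicate 3 at ZT18, and on average without jaz4-1 at ZT6 replicate 1 (adjusted p 0.0561 to 0.254).

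**Figure D4:**
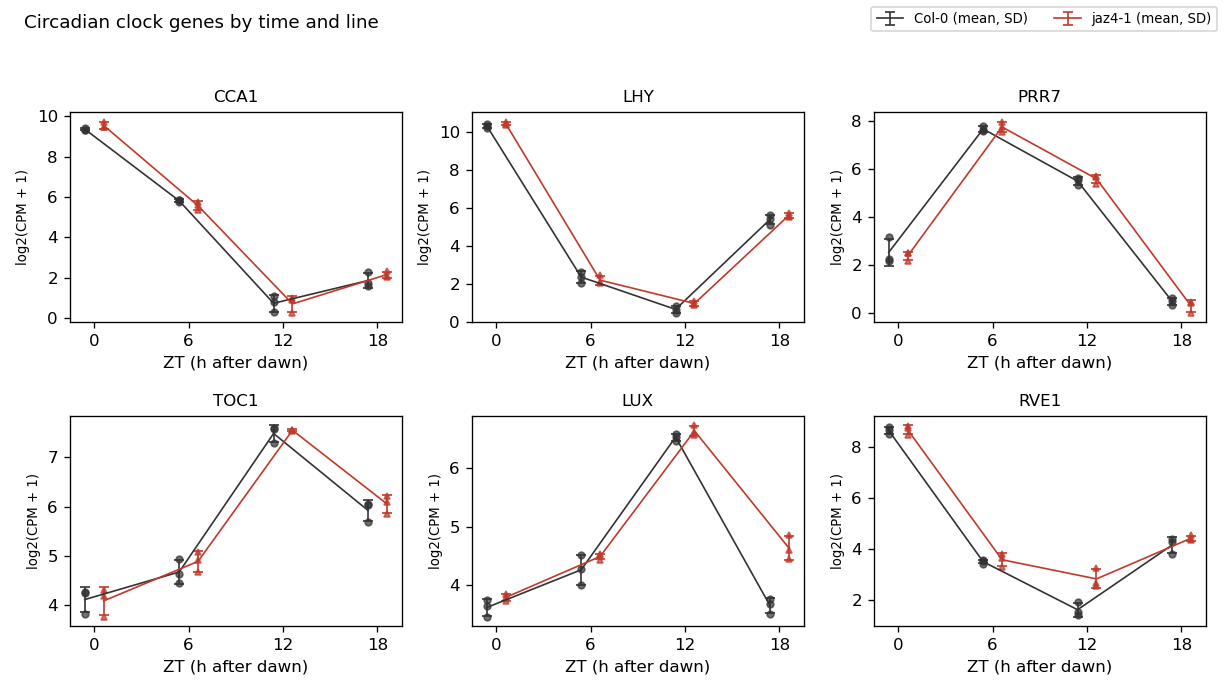
Log2(CPM + 1) on the y axis against hours after dawn (ZT) on the x axis for 6 clock genes, with points for single libraries (3 per line and time), lines through the means and bars of 1 SD. Of these genes, limma called LUX at ZT18 (log2 fold change 1.07) and RVE1 at ZT12 (1.58).

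The jasmonate lists held few called genes. Of 10 measured JAZ repressor genes 0 were called by limma on average, with 4 at an unadjusted p under 0.05, 1 adjusted over the list alone, 0 by edgeR or limma-voom and 2 by DESeq2; JAZ6 differed by 0.50 ± 0.16 (adjusted p 0.0720) and JAZ7 by 1.32 ± 0.60 (0.210). The list ranked higher at ZT12 (median 0.64; camera adjusted p 0.000181; adjusted p = 0.427 with an estimated correlation) and was not called on average (0.0941). Jasmonate catabolism genes ranked higher at ZT12 (camera adjusted p 0.00314; adjusted p = 0.648 with an estimated correlation), with 0 of 10 members called by limma, 2 at an unadjusted p under 0.05 and 0 by edgeR, DESeq2 or limma-voom. Without jaz4-1 at ZT12 replicate 3 the JAZ repressor call was lost (adjusted p 0.812, median 0.06), and the catabolism list turned downward without a call (0.590). Without jaz4-1 at ZT12 replicate 1 the JAZ repressor median at ZT12 was 1.15, and 2 of these genes were called on average. Neither jasmonate synthesis (13 genes) nor jasmonate response (12) was called as a list at any time, with adjusted p of at least 0.177 and 0.276. At ZT0 the median of jasmonate synthesis was 0.10 and its mean -0.04, while jasmonate catabolism had a downward camera test with a median of 0.05.

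Flavonoid and anthocyanin genes ranked lower at ZT0, ZT6, ZT12 and on average (camera adjusted p 0.00219, 0.000354, 0.0236 and 2.64e-05; adjusted p = 0.760, 0.696, 0.808 and 0.524 with an estimated correlation). On average 0 of 15 were called by limma, with 9 lower at an unadjusted p under 0.05, 8 adjusted over the list alone, 1 by edgeR, 6 by DESeq2 and 0 by limma-voom. Their median was -0.82, with GL3 at -1.02 ± 0.30 (adjusted p 0.0531). Without single libraries up to 3 members were called on average (Col-0 at ZT18 replicate 1), 2 without jaz4-1 at ZT12 replicate 3, and 1 without Col-0 at ZT0 replicate 3, Col-0 at ZT12 replicate 1, jaz4-1 at ZT0 replicate 2, jaz4-1 at ZT6 replicate 3 or jaz4-1 at ZT18 replicate 2. The camera calls were lost at ZT0 without jaz4-1 replicate 3 (adjusted p 0.0964) and at ZT12 without jaz4-1 replicate 1 (0.598), and the ZT12 direction turned without Col-0 replicate 3 (0.0441).

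Across the 21 lists that could be tested, 35 of 105 list tests were called by camera, 24 upward and 11 downward. With an estimated correlation 0 were called (14 at an unadjusted p under 0.05), and fry called 12. Those were salicylate and immunity at ZT0, ZT6 and on average, and sugar starvation and touch at ZT6, ZT12 and on average. The others were aliphatic glucosinolates and heat shock at ZT6 and the clock on average (fry adjusted p 6.50e-05 to 0.0454 over all 12). Salicylate and immunity at ZT12 and ZT18 was not called by fry (adjusted p 0.120 and 0.114). Among 100 divisions of the 24 libraries within times, 24 gave at least 35 list calls, so chance is not excluded for this number. Photosynthesis genes ranked higher at ZT6, ZT18 and on average (camera adjusted p 0.000647, 0.0148 and 0.0360; adjusted p = 0.760, 0.808 and 0.846 with an estimated correlation). None of the 19 was called at ZT6 (0 by limma, 6 at an unadjusted p under 0.05, 0 by edgeR, DESeq2 or limma-voom). Starch breakdown genes ranked higher at ZT6 (adjusted p 0.00149; adjusted p = 0.467 with an estimated correlation), with 0 of 12 called by limma, 2 adjusted over the list alone, 5 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by edgeR or limma-voom; 2 were called without Col-0 at ZT0 replicate 1. Iron deficiency genes ranked lower at ZT12 and higher at ZT18 (adjusted p 0.00727 and 2.68e-06; adjusted p = 0.760 and 0.427 with an estimated correlation), with 0 of 12 called at either time by limma, edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05.

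Senescence genes ranked higher at ZT12 (adjusted p 0.000213; adjusted p = 0.467 with an estimated correlation), with 0 of 16 called by limma, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by edgeR or limma-voom. Cold response genes ranked lower at ZT12 (0.0236; adjusted p = 0.467 with an estimated correlation), with 0 of 14 called by limma, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by edgeR or limma-voom. The list of growth, PIF and auxin genes ranked lower at ZT18 (0.0163; adjusted p = 0.427 with an estimated correlation), heat shock genes higher at ZT18 (0.0300; adjusted p = 0.196 with an estimated correlation), touch genes higher at ZT0 (0.00431; adjusted p = 0.760 with an estimated correlation) and aliphatic glucosinolate genes lower at ZT0 (0.000251; adjusted p = 0.524 with an estimated correlation). Lists of flowering (20 measured), abscisic acid and drought (12), indole glucosinolate (10) and floral organ (3) genes were not called at any time or on average. Median and mean had opposite signs for cold response (-0.04 and 0.16) at ZT0, senescence (0.21 and -0.01) at ZT6, floral organ genes (-0.03 and 0.14) at ZT12, and flowering (-0.02 and 0.09), senescence (-0.02 and 0.06), indole glucosinolate (0.01 and -0.15) and sugar starvation (-0.03 and 0.00) at ZT18. In tests that were not called, camera pointed up for cold response at ZT6 (median -0.00, mean -0.14) and down for indole glucosinolate genes on average (median 0.03, mean 0.02). Root markers were not tested, since 2 of 9 were measured; the root glucosidase gene PYK10 had 45052 reads in Col-0 and 35181 in jaz4-1.

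Of these camera calls, that of photosynthesis was lost without Col-0 at ZT6 replicate 3 at ZT6, without Col-0 replicate 3 or jaz4-1 replicate 1 or 3 at ZT18, and on average without Col-0 at ZT0 replicate 1, ZT6 replicate 3, ZT12 replicate 1 or ZT18 replicate 3, or jaz4-1 at ZT0 replicate 3, ZT6 replicate 1, ZT12 replicate 1 or 2 or ZT18 replicate 1 or 3 (adjusted p 0.0520 to 0.514). Senescence at ZT12 was lost without jaz4-1 replicate 3 (0.665), and cold response at ZT12 without Col-0 replicate 3 or jaz4-1 replicate 1 (0.228 and 0.161). Iron deficiency at ZT12 was lost without jaz4-1 replicate 1 (0.0981) and turned upward without Col-0 replicate 3 (0.00666). Growth, PIF and auxin at ZT18 was lost without Col-0 replicate 1 or jaz4-1 replicate 2 (0.320 and 0.0661), heat shock at ZT18 without Col-0 replicate 1 or jaz4-1 replicate 1 (0.146 and 0.149), and heat shock at ZT6 without jaz4-1 replicate 1 or 3 (0.0835 and 0.0713).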

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

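The tests of genes chosen at the other times for a mislabelled library, of linkage to JAZ4, of seed stocks, of collection nearer to dusk at ZT6, and of the clock genes and the Col-0 libraries left out at ZT12, were chosen after the results were seen.

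The difference between jaz4-1 and Col-0 depended on the time in 38 genes, by an F test of the time dependence itself (limma, Benjamini-Hochberg). Among genes with a symbol and a mean of at least 1 CPM, adjusted p of the 10 with the smallest p were 0.00299 for LLP, 0.0173 for BT5 and APR1, 0.0207 for OFUT20, BT2 and TEM2, 0.0228 for RZPF34 and PCC1, 0.0233 for Cand1 and 0.0242 for OXS3. From ZT0 to ZT18 the log2 fold changes were -0.14, 1.87, 0.67 and -0.20 for OFUT20, -0.07, 0.69, 1.28 and -0.33 for RZPF34, and -0.70, 0.32, 1.45 and -0.32 for OXS3. Of 100 splits of the libraries within times, 7 gave as many genes as the real one, with 907 as the highest other, so chance is not excluded for this count.

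Salicylate and immunity genes were higher in jaz4-1 on average, with 8 of 19 called. A single deviating library as the cause is argued against by the fits that leave out each library, in which at least 8 members were called. With gene length and GC trends removed 8 members were called, which argues against such a trend. A difference of line remains open as a biological explanation, and it cannot be set apart here from a difference of the seed stocks, since the series holds 1 jaz4 line.

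Sugar starvation genes were higher in jaz4-1 at ZT6, with 4 of 7 called and a median of 1.16. Without the 2 libraries with few detected genes the median was 1.13 while the calls fell to 1, with fewer libraries left to test on; with length and GC trends removed 4 members were called. Collection of jaz4-1 nearer to dusk is argued against, since the list fell by 1.55 from ZT6 to ZT12 in Col-0. That fall alone decides the test, whatever the clock genes show. The difference of the clock genes at ZT6 had a slope of 0.00357 on their own change over that time (95% interval over genes -0.0349 to 0.0420, lowest bound -0.0595 without jaz4-1 replicate 3, highest 0.0698 without Col-0 replicate 3). Genes are not independent replicates, so this interval does not hold the spread between libraries. Collection of jaz4-1 earlier than Col-0 was not tested and stays open. At ZT12, 77.6% of the 58 higher genes (45) lay higher at ZT18 than at ZT12 in Col-0, against 50.6% of all tested genes, a share that the choice of genes on the same Col-0 ZT12 libraries can raise; for genes called without 1 of these and set against it, the shares were 84.6%, 81.5% and 62.2% (replicates 1 to 3). The median difference of the 58 was 2.50 times their median Col-0 change (2.83, 2.83 and 3.28 for the genes set against a library left out). That multiple lies past the Col-0 level at ZT18, so no delay up to ZT18 could be expected to reach it. Comparing the clock genes with it therefore decides nothing. The clock genes had a slope of 0.0287 (95% interval over genes -0.0165 to 0.0739, highest bound 0.0887 without Col-0 replicate 3). Genes are not independent replicates, and difference and change share the Col-0 ZT12 libraries. Without single libraries the slope was 0.0203 to 0.0407, which argues against a delay that moved the clock genes by a large part of their change to ZT18. A short delay past the end of the light stays open, since no library lies between ZT12 and ZT18.

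The 7 genes called at all 4 times separated the lines in all libraries. In genes chosen at the 3 other times, 24 of 24 libraries lay on the side of their own line, which argues against a mislabelled library. For the 5 genes on chromosomes other than that of JAZ4, their place in the reference argues against linkage to its locus. Whether the line carries rearrangements or further insertions was not examined. Of the 2 on chromosome 1, 0 lay within 100 tested genes of JAZ4 in TAIR10.1, and looser linkage stays open. A difference of the seed stocks that does not come from JAZ4 may account for such genes and cannot be told apart from an effect of the insertion, because the series holds 1 jaz4 line.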

How the results depend on the processing

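Alternatives chosen after seeing the data were edgeR on recovered reads, TMM scaling, pseudocounts, length and GC trends removed, log2(value + 1) for the lists and the fit without both libraries with few detected genes. No setting other than those named here moved a count of genes by over 1.5 times, and the cause was not tested unless stated. DESeq2 called 364 genes at ZT0, 1154 at ZT6, 163 at ZT12, 54 at ZT18, 1662 on average and 210 for dependence on time. With only the libraries compared, which leaves fewer degrees of freedom, the counts were 29 at ZT0 and 22 at ZT12. A log2 fold change of 1 or more left 94 at ZT0, 211 at ZT6 and 121 on average. Without both libraries with few detected genes the counts were 117 at ZT0, 243 at ZT6 and 5 for dependence on time, and the median phase difference was -0.163 h (permutation p 0.0160). List calls were 0 with an estimated correlation and 12 with fry.

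Leaving out 1 library at a time gave 93 to 663 genes at ZT0, 173 to 1208 at ZT6, 22 to 126 at ZT12, 15 to 33 at ZT18, 628 to 1435 on average, 7 to 60 for dependence on time, 8880 to 10092 over time in Col-0, 9514 to 10995 in jaz4-1, -0.168 to -0.0875 h for the phase and 32 to 38 list calls. Of the 148 calls of named genes, 10 were of dependence on time, an F test without a direction. None of the other 138 turned direction under any setting run. Among all 148, calls were lost: 39 without both libraries with few detected genes, 28 with limma-voom, 9 with edgeR, 8 with length and GC trends removed, 8 with no filter, 3 and 1 with pseudocounts of 0.5 and 4, and 1 each with DESeq2, TMM scaling and a mean of at least 1 CPM. With only the libraries compared 33 of 100 were lost, and with a log2 fold change of 1 or more, which removes smaller changes by construction, 35 of 138. Uncalled results of named genes gained a call 3 times with DESeq2, 1 time with limma-voom and 4 times with 1 library left out.

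With the replicate number as a replicate block, counts were 195, 601, 70 and 31 from ZT0 to ZT18, 954 on average and 51 for dependence on time, with 34 list calls and a phase difference of -0.129 h. The block ended 5 of the 148 calls, HR3, TEM2, FMOGSOX1 and ERF4 at ZT6 and ATHB-51 on average (adjusted p up to 0.0592), and the list call of photosynthesis on average. Same-numbered libraries of both lines at a time deviated together with a median r of 0.129 (-0.0978 to 0.327, 7 of 12 pairs over 0.1), against -0.0513 for differently numbered ones (2 of 24 over 0.1). Since not every pair was over 0.1, the numbers were not taken to pair the libraries. That rule is no test of pairing, and the higher values of same-numbered libraries leave pairing within a time open. The block was shared by all times, so it does not model such pairing. Of 24 libraries, 13 lay closest to their own number.

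Directions turned for uncalled clock genes, for JAZ4 at ZT6 and for list tests at ZT12, in the log2 values and adjusted p that follow. Medians of called lists turned as well: at ZT12 to -0.105 for jasmonate catabolism without jaz4-1 replicate 3, to -0.00654 for the clock, 0.494 for flavonoid and anthocyanin genes and 0.342 for iron deficiency without Col-0 replicate 3, to 0.147 for flavonoid and anthocyanin genes without jaz4-1 replicate 1, and at ZT18 to -0.00518 for photosynthesis without Col-0 replicate 3. The uncalled median of sugar starvation at ZT18 (-0.0326) was 0.00535 without jaz4-1 replicate 2. At ZT0, PRR9 was -0.127 by DESeq2, -0.0554 by limma-voom, -0.144 by edgeR and -0.253 without both libraries with few detected genes, and ELF4 -0.258 by DESeq2, -0.241 by edgeR and -0.393 without those libraries, where TOC1 was 0.106 and GI -0.0569. LHY at ZT6 was 0.0120 with size factors over 24 libraries, 0.00466 by DESeq2 and 0.00582 by edgeR, and JAZ4 at ZT6 was 0.357 without both libraries. PRR9 was 0.0613 at ZT12 with a pseudocount of 0.5, and on average -0.0509 with a pseudocount of 4 and -0.0203 without both libraries. ELF4 on average was -0.110 by DESeq2, -0.105 by edgeR, -0.0283 with a pseudocount of 4 and -0.0904 without both libraries.

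With 1 library left out, values at ZT0 ran from -0.253 to 0.362 for PRR9, -0.331 to 0.146 for PRR7, -0.124 to 0.106 for TOC1, -0.0569 to 1.38 for GI and -0.393 to 1.05 for ELF4. At ZT6 they ran from -0.163 to 0.107 for CCA1, -0.203 to 0.142 for LHY and -1.15 to 0.357 for JAZ4. At ZT12 they ran from -0.654 to 0.610 for CCA1 and -0.560 to 0.870 for PRR9, and at ZT18 from -0.324 to 0.918 for PRR9. On average they ran from -0.0195 to 0.297 for CCA1, -0.177 to 0.268 for PRR9, -0.353 to 0.0375 for PRR7 and -0.154 to 0.206 for ELF4. Adjusted p of the lists at ZT12 ran from 1.63e-06 to 0.590 for jasmonate catabolism, 2.28e-06 to 0.598 for flavonoid and anthocyanin genes and 1.56e-08 to 0.0981 for iron deficiency.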

Other observations

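The tests of TIR-NBS-LRR genes and of receptor-like kinases were chosen after the results were seen.

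Genes described in the deposited annotation as of the TIR-NBS-LRR, TIR-NBS or TIR-domain kind, most of them intracellular immune receptors, were called higher in jaz4-1 more often than other genes on average and at ZT6. On average over times 17 of 65 (26.2%) were called higher, against 3.20% of the other genes (odds ratio 10.7, 95% interval 5.74 to 19.1; Fisher's exact p 2.04e-11, 2-sided), and at ZT6 15 of 65 (23.1%), against 2.12%, or 8 without Col-0 at ZT6 replicate 1. At ZT0 3 were called (Fisher's exact p 0.0121), or 6 without Col-0 at ZT0 replicate 3, and at ZT12 1 (p 0.175), which was lost without Col-0 replicate 1 or 3 or jaz4-1 replicate 2 or 3 of ZT12, while 2 were called without jaz4-1 replicate 1. At ZT18 limma called 0 (Fisher's exact p 1), with 3 at an unadjusted p under 0.05 and 0 by edgeR, DESeq2 or limma-voom. AT5G41750 rose by 1.56 ± 0.27 and AT5G41740 by 1.18 ± 0.15 on average (SE, n = 12 libraries per line). Members of this class are alike in sequence, so the assignment of their reads is uncertain.

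Receptor-like kinase genes were called higher more often than other genes on average, at ZT0 and at ZT6. At ZT6, 23 of 240 (9.58%) were called higher and 1 lower, against 2.1% higher among other genes (odds ratio 4.95, 95% interval 3.04 to 7.73; Fisher's exact p 3.38e-09, 2-sided), with 15 higher without Col-0 at ZT6 replicate 1 and 13 without jaz4-1 at ZT6 replicate 2. At ZT0 19 of 240 were called higher (7.92%, against 0.645%), and on average 41 (17.1%, against 3.11%). At ZT12 1 was called (0.417%, against 0.294%; Fisher's exact p 0.511), which was lost without jaz4-1 at ZT12 replicate 2. At ZT18 3 were called (Fisher's exact p 0.00235), or 1 without Col-0 replicate 3 or jaz4-1 replicate 1, and all 3 calls were lost without Col-0 replicate 2 or jaz4-1 replicate 3. DESeq2 called 5 at ZT18, as did limma without both libraries with few detected genes. RLK1 rose by 1.60, WAK1 by 1.28, WAKL6 by 1.01, SOBIR1, a co-receptor of receptor-like proteins, by 0.94 and CRK10 by 0.73 on average. Genes are not independent replicates, so these Fisher tests describe the libraries at hand. Across genes, the correlation (rho) of log2 fold change with gene length was 0.120, 0.154, -0.0202 and 0.0837 from ZT0 to ZT18 and 0.134 on average. Counts of both families with length and GC trends removed are not given here, so a part of such trends in them stays open.

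Genes near JAZ4 were tested for more frequent change, in a test laid out before its result was seen. Of 200 tested genes (100 on each side in TAIR10.1), 8 (4%) were called on average, against 4.69% of the others (odds ratio 0.847, 95% interval 0.359 to 1.71; Fisher's exact p 0.866, 2-sided), which does not bear out the hypothesis.

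Splits of the same libraries into other groups were fitted in the same way. On average over times, the real split gave 918 genes and the highest of the others 4 (1 of 100 as large, the smallest share that 100 splits allow), so chance alone is unlikely. For change over time, the real values were 9636 in Col-0 and 10491 in jaz4-1 and the highest others 6886 and 7800 (1 of 100 as large in each), so chance alone is unlikely. For the lists, 24 of 100 splits gave as many calls as the real 35, with 42 as the highest other, and chance is not excluded. At single times 3 against 3 libraries make 10 splits, too few to decide. The real and highest other values were 578 and 2 at ZT6, 63 and 0 at ZT12 and 27 and 0 at ZT18. At ZT0 they were 181 and 1008 (2 of 10 as large). The split with 1008 set Col-0 replicates 1 and 2 with jaz4-1 replicate 2 against the others, which points to a structure of the ZT0 libraries beside the line.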
